A study of Mus musculus with 18 samples.

How the data were processed

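Circular RNA was measured in the livers of 18 male C57BL/6 mice by sequencing of RNA depleted of ribosomal RNA. Circular RNAs are closed loops in which the end of a downstream segment is joined back to the start of an upstream one, and they are counted by reads that cross this back-splice junction. Per the labels' protocols, 45 mice entered the experiment at 6 weeks of age, 15 per group, and 6 per group were sequenced in week 22. Controls received water by gavage and olive oil by intraperitoneal injection. The CCl4 group received water and carbon tetrachloride (CCl4), a liver toxin used here to induce liver cancer. The treated group received CCl4 and Pien Tze Huang (PZH), a traditional Chinese medicine, given daily by gavage. The labels of the 6 treated samples and the growth protocol write PTH, which was taken as the same treatment. RNA was extracted with TRIzol, libraries were made with a NEBNext kit, and reads of 150 bp were sequenced from both ends on a HiSeq 4000.

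The deposited table holds CPM values, that is, back-splice read counts scaled to a library total chosen by the authors, for 434 circular RNAs named by chromosome, start and end, without strand. Per the submitters' processing notes, FastQC 0.11.9, cutadapt 4.2, HISAT2 2.2.1, StringTie 2.1.5 and Bowtie2 2.5.1 were used with genome build GRCm38. The circular RNA caller, the total behind the CPM and the filter that left these 434 are not given in the sources used here. Every circular RNA in the table was above 0 in at least 9 of the 18 libraries.

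In each library the values were whole multiples of the value of 1 read, so whole reads could be recovered. All 7812 values (100%) lay within 0.1 of a whole number. The recovered reads numbered 900 to 2840 per library and 25803 in all, and the median non-zero value was 3 reads. The total implied by the value of 1 read ran from 3.27 M to 22.3 M reads (M, the scale of CPM). A value listed at 0 allows up to 3 reads, which is 0.135 CPM in control 3 and 0.918 CPM in control 2. Such floors and intervals cover counting error only, since reads made by PCR are not independent molecules. No pair of libraries within a group agreed within sampling noise: over 45 pairs, the lowest chi-square per degree of freedom was 2.79 and the highest p was 3.87e-17.

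Host genes were assigned by position: a circular RNA was given the gene of GRCm38.p6 that contains both of its ends, the shortest protein-coding one where several did. A host was found for 429 of 434, in 374 genes, of which 44 host more than 1. Of the 429, 419 lie in protein-coding genes, 4 in long non-coding RNA genes and 6 in pseudogenes. Exons and introns were not used here, and without strand an overlapping antisense gene cannot be told from the host. The level of a circular RNA is not the level of its host gene, which was not analysed here. Circular RNAs in the Mug, Cfhr, Ces1, Ugt2b and Mup families and in pseudogenes such as Gm9762 and Mug-ps1 are uncertain, since near-identical copies share reads.

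The main test was limma 3.58.1 (R 4.3.3) on log2(CPM + 0.13655), the pseudocount being the median over libraries of the smallest non-zero value. All 18 libraries entered 1 fit of 3 group means with an intensity trend; tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low values. The planned filter, non-zero in 6 or more libraries, removed 0. Numbers of circular RNAs detected and summed CPM per library were compared by exact permutation tests, and presence by Fisher's exact test. The 15 host gene lists were fixed before the data were examined, as were the tests, most alternative settings and the rule for named circular RNAs. Lists with 5 or more circular RNAs were tested with camera at a preset correlation of 0.01, and also with an estimated one. A replicate number in the labels names a mouse; the check of pairing stands with the alternatives.

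The rule for named circular RNAs took, per comparison, those past the threshold, then those of smallest p up to 10 in all, the 5 of highest mean CPM, and in each list the called members or else the member of smallest p. One list member that the rule takes is not reported here. The other circular RNAs of Ttc39c and Bckdhb were added after their values were seen. Alternatives were other pseudocounts, filters and scalings, quantile normalization, array weights, a rank test, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a block on replicate number, and each library left out. Subsets of controls were used as well: controls 2, 3 and 4 were deposited later than the other 15 libraries. Alternatives chosen after seeing the data were values scaled to the table's own reads, abundant zeros set to missing, edgeR with the implied totals, controls 3 and 4 left out together, and single-copy coding hosts only. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

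The tests were tried on simulated data for the comparison of CCl4 with control, with 40 of 434 circular RNAs changed. limma called 4.08% of those changed 4-fold, 12.6% of those changed 8-fold, 27.2% at 16-fold and 38.9% at 32-fold, and 0.0942% of the unchanged. With 200 changed, it called 13.8%, 38.0%, 52.3% and 65.5% at these folds, and 0.912% of the unchanged. Simulated reads rose in proportion to the implied totals, which the recovered reads did not. The zeros of abundant circular RNAs described below were not added to the simulated data either. These rates therefore need not hold for the measured data.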

Results

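Circular RNA was profiled in mouse liver in week 22 in 3 groups of 6 mice: controls, mice given CCl4, and mice given CCl4 with PZH. The comparison of CCl4 with control asks which circular RNAs differ in the liver cancer model. The comparison of CCl4+PZH with CCl4 asks what the treatment changes, and that of CCl4+PZH with control asks what separates treated livers from normal ones. The table holds 434 circular RNAs, and 246 (control 3) to 350 (CCl4+PZH 2) were above 0 in a library. Summed CPM ran from 40.4 (control 3) to 550 (control 4), a range of 13.6-fold that lay within the controls, while the recovered reads ran from 900 to 2840, a range of 3.16-fold.

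Over all 18 libraries, the circular RNA of highest mean level lay in Ube3a, a ubiquitin ligase gene, at 5.45 ± 6.21 CPM (SD, n = 18). It was followed by one in Rmdn2 at 4.39 ± 3.82 CPM, one in Gramd1c at 3.89 ± 3.43 CPM, one on chromosome 3 outside annotated genes at 3.29 ± 3.38 CPM, and one in Alg12 at 2.31 ± 1.51 CPM. The order by mean CPM differed by group: Ube3a was highest in controls (8.76 ± 9.57 CPM, SD, n = 6), that on chromosome 3 in CCl4 livers (4.89 CPM, Ube3a 2.58 CPM) and Rmdn2 in CCl4+PZH livers (5.25 CPM, Ube3a 5.01 CPM). By recovered reads the order of these 5 was another. Rmdn2 led in controls (284 reads, Ube3a 278), and that on chromosome 3 led in CCl4 (276 reads) and in CCl4+PZH livers (238 reads, Rmdn2 222). Detected circular RNAs numbered 294 ± 29.6 in controls, 289 ± 20.3 in CCl4 and 310 ± 24.8 in CCl4+PZH livers (SD, n = 6 each). The smallest exact permutation p of the 3 pairs was 0.13, adjusted p = 0.39. Summed CPM was 242 ± 190 in controls, 149 ± 36.4 in CCl4 and 208 ± 50.0 in CCl4+PZH (SD, n = 6 each). CCl4+PZH exceeded CCl4 by 59.0 CPM (exact permutation p = 0.0455), which did not pass adjustment over the 3 pairs (adjusted p = 0.136). Of the 12 libraries left out singly, only CCl4+PZH replicate 1 changed this. Without it the difference was 77.4 CPM and passed (exact permutation, adjusted p = 0.013). The highest adjusted p of these 12 exact permutation tests was 0.273. The CCl4 and CCl4+PZH libraries all belong to the first deposit. Against the controls the exact adjusted p-values were 0.484 for CCl4 and 0.693 for CCl4+PZH. With controls 1, 5 and 8 alone, at 159 ± 41.4 CPM (SD, n = 3), the exact p-values were 0.714 and 0.167.

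**Figure D1:**
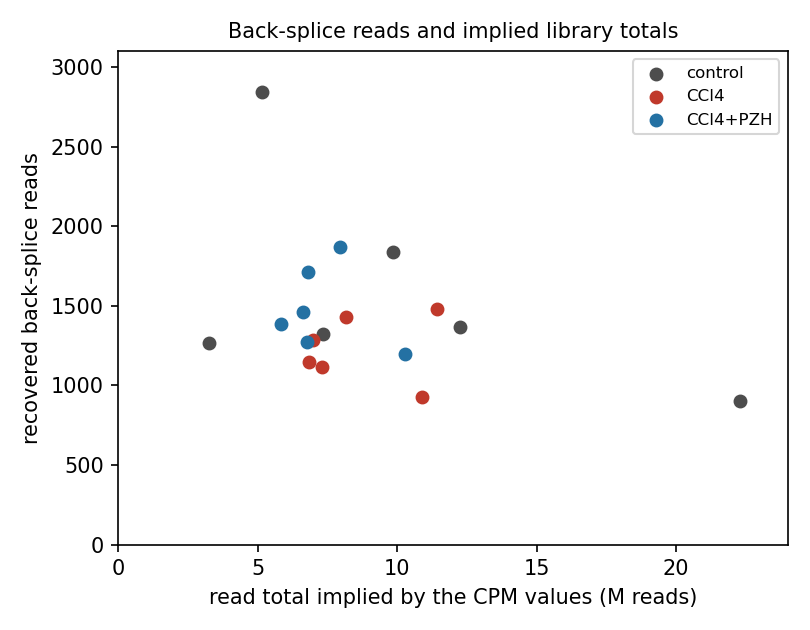
Recovered back-splice reads of each library (vertical axis) against the read total implied by its CPM values (horizontal axis, M reads); each point is 1 mouse liver, coloured by group. Control 3 has the largest total, 22.3 M, with 900 reads, and control 4 has 2840 reads at 5.17 M.

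CCl4 livers differed from controls in 3 circular RNAs, 2 higher and 1 lower. A circular RNA on chromosome 3, from 5860581 to 5860757 (177 bp), which lies in no annotated gene, was listed at 0 in 6 of 6 controls and stood at 4.89 ± 3.62 CPM in CCl4 livers (SD, n = 6), above 0 in 5 of 6. Its mean in CCl4 was 11.3-fold the floor of 3 reads per library averaged over the controls (0.432 CPM). This ratio is not a lower bound, since the floor covers counting error only and abundant circular RNAs were often listed at 0. A circular RNA in Zc3h7a, which encodes a zinc finger protein (chromosome 16, 11144001 to 11144173), stood at 2.25 ± 1.64 CPM in CCl4 and 0.459 ± 1.12 CPM in controls (SD, n = 6 each), above 0 in 5 and 1 libraries. A circular RNA in Ttc39c (chromosome 18, 12684837 to 12698059) was lower in CCl4, at 0.151 ± 0.149 CPM against 1.77 ± 0.911 CPM (SD, n = 6 each), and its groups did not overlap.

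On the log2(CPM + pseudocount) scale, limma gave 4.39 (SE 0.80, adjusted p = 1.97e-05) for the circular RNA on chromosome 3, 2.80 (SE 0.74, adjusted p = 0.0316) for Zc3h7a and −2.72 (SE 0.74, adjusted p = 0.0353) for Ttc39c. The median over all 434 was −0.28; relative to it the values were 4.68, 3.08 and −2.43. With values scaled to the table's own reads the median was −0.03. The calls for Zc3h7a and Ttc39c were lost when any of controls 1, 4 and 8 or CCl4 1, 2, 7 and 8 was left out (1 call each), and 6 were called without control 3; without control 2 Ttc39c was lost and without control 5 Zc3h7a was lost.

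**Figure D2:**
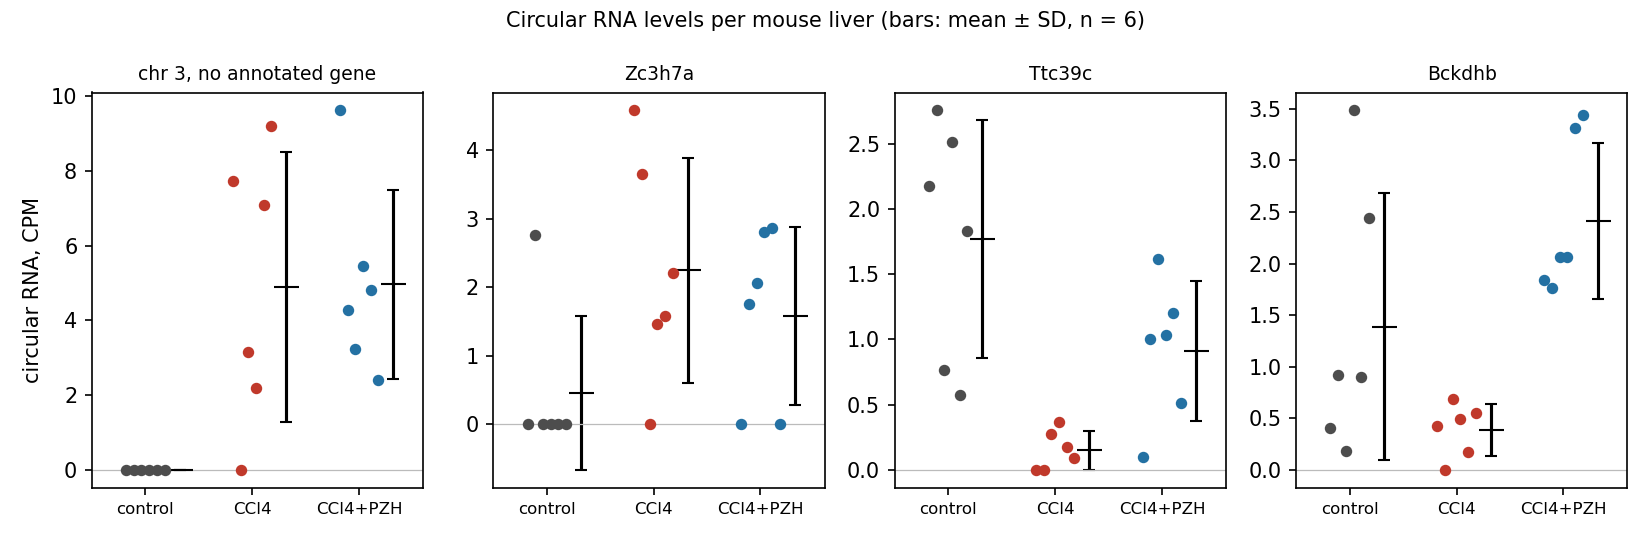
CPM (vertical axis, linear) of 4 circular RNAs in each mouse liver of the control, CCl4 and CCl4+PZH groups; points are single mice and bars are mean ± SD (n = 6). The chromosome 3 circular RNA is at 0 in 6 of 6 controls, Ttc39c is at 0.151 CPM on average in CCl4 livers, and Bckdhb is at 2.41 CPM in CCl4+PZH and 0.388 CPM in CCl4 livers.

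The other circular RNAs of smallest p in this comparison did not pass. Higher values in CCl4 were measured for Psd3 (log2 2.12, adjusted p = 0.109), for the kinase gene Tlk1 (log2 2.17, adjusted p = 0.154) and for the kinase gene Vrk2, listed at 0 in 6 of 6 controls and at 0.441 ± 0.426 CPM in CCl4 (SD, n = 6; limma adjusted p = 0.199). The mean of Vrk2 lay below the floor of 3 reads in controls 2 and 4 (0.918 and 0.581 CPM) and above it in controls 1, 3, 5 and 8. edgeR with TMM on the recovered reads placed Tlk1 (adjusted p = 0.0022) and Vrk2 (adjusted p = 0.0239) past the threshold. DESeq2 on the same reads and edgeR with the implied totals called neither. Over 41 alternatives Tlk1 passed in 3 and Vrk2 in 1. Lower values in CCl4 were measured for Mlxipl, a carbohydrate-responsive regulator of fat synthesis, with log2 −2.15 (adjusted p = 0.155), the RNA-binding protein gene Hnrnpu, with −2.11, the paraoxonase gene Pon1, with −2.04, and the pseudogene Gm9762, with −2.13 (adjusted p = 0.199 for these 3). The 2 further circular RNAs of Ttc39c, chosen after their values were seen, had log2 values of −1.51 (adjusted p = 0.535) and −1.03 (adjusted p = 0.702).

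No host gene list passed camera in CCl4 against control, where the smallest adjusted p was 0.362. The 5 circular RNAs of lipid and fatty acid genes all had negative log2 values, with a median of −0.89 (p = 0.0315, adjusted p = 0.362; p = 0.13 with an estimated correlation). Adjusted over the list alone, 1 of them fell, that of Mlxipl; over all tested, 0 did. Of 9 in bile acid and cholesterol genes, from 5 hosts, 3 had positive values; adjusted over the list alone 1 fell, that of Slco1b2, a hepatocyte uptake transporter, at 141663578 to 141672313 of chromosome 6 (log2 −1.88, adjusted p = 0.201 over all tested). The 4 circular RNAs of drug metabolism genes had negative values, with a median of −0.95 and Ces1c at −1.61 (adjusted p = 0.403). Those of amino acid, urea cycle and glucose genes had 3 positive values of 12, with Cth, an enzyme of cysteine synthesis, at −1.48 (adjusted p = 0.535).

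Among lists of other cell types, the 4 circular RNAs of macrophage genes, 3 of them in Adgre1 and 1 in Mertk, had positive values with a median of 0.83. Adjusted over the list alone 1 rose, in Adgre1, a macrophage marker, at 0.519 ± 0.477 CPM in CCl4 and 0.0453 ± 0.111 CPM in controls (SD, n = 6 each; limma log2 1.61, adjusted p = 0.259 over all tested). The only member of the lymphocyte list, in Ikzf1, had log2 1.02 (adjusted p = 0.704), and the only member of the matrix and stellate cell list, in Mmp15, had log2 0.48 (adjusted p = 0.862). Endothelial, cholangiocyte and red blood cell genes had 0 members. None passed among the 3 of plasma protein genes (Kng2 −0.21, adjusted p = 0.944), the 3 of liver cancer genes (Egfr −1.08, adjusted p = 0.704) or the 1 of cell cycle genes (Brca2 0.07, adjusted p = 0.982). The 18 of well-studied hosts had a median of −0.34, with Rere at −1.62 (adjusted p = 0.246). The 10 of RNA processing and chromatin genes had a median of 0.07 and a mean of −0.20; adjusted over the list alone 1 fell, that of Hnrnpu.

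Treatment with PZH left 0 of 434 circular RNAs past the threshold against CCl4 alone by limma, with 24 at an unadjusted p under 0.05; edgeR and DESeq2 also called 0. So did an exact rank test, whose smallest p of 0.00216 cannot pass over 434 tests unless many circular RNAs reach it. The smallest p belonged to a circular RNA in Bckdhb, which encodes a subunit of the branched-chain keto acid dehydrogenase (chromosome 9, 83952524 to 83991822). It stood at 2.41 ± 0.755 CPM in CCl4+PZH and 0.388 ± 0.254 CPM in CCl4 (SD, n = 6 each), and the groups did not overlap; limma gave log2 2.45 (SE 0.79, adjusted p = 0.79), or 2.22 relative to the median of 0.23. By chance 0.94 of 434 would separate 2 groups of 6 in this way. Adjusted over the list of amino acid, urea cycle and glucose genes alone, 1 rose, this one. The 2 further circular RNAs of Bckdhb, chosen after their values were seen, had log2 0.53 (83952283 to 83991822, which has the same end; adjusted p = 0.954) and −0.12 (83988776 to 84012619; adjusted p = 0.992).

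Of the 3 circular RNAs called in CCl4 against control, that of Ttc39c stood at 0.913 ± 0.535 CPM in CCl4+PZH (SD, n = 6), a log2 difference from CCl4 of 1.80 (limma SE 0.74, adjusted p = 0.804). That of Zc3h7a stood at 1.58 ± 1.30 CPM (log2 −0.75, adjusted p = 0.896), and that on chromosome 3 at 4.97 ± 2.53 CPM (log2 0.70, adjusted p = 0.947). Opposite moves, called one way by CCl4 and the other way by PZH, numbered 0. Values that did not pass (adjusted p = 0.804 each) were higher in CCl4+PZH for Arih1 (log2 1.60), Msrb3 (1.84), Gm39583 (1.64), Mug-ps1 (1.63), Lrrc28 (1.54), Ube2g2 (1.54) and Gm9762 (1.65), and lower for Psd3 (−1.48). Cyp1a2, a drug-metabolising enzyme of the liver, had log2 1.34, Egfr 1.59, Mlxipl 1.15, Rbm33 1.15 and Adgre1 −1.01 (adjusted p = 0.804 each).

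No list passed camera for CCl4+PZH against CCl4. The lipid list had 5 positive values of 5 (median 0.40, p = 0.365), and the amino acid list 9 of 12 (median 0.53, p = 0.0713, adjusted p = 0.362; p = 0.257 with an estimated correlation). The bile acid list had a median of −0.16, with another circular RNA of Slco1b2, at 141648489 to 141657606, at 0.79, and the RNA processing list a median of 0.25. For well-studied hosts the median was 0.07 while camera pointed down (adjusted p = 0.609), with Cdk8 at 1.01. In lists below the size for a test, medians were 0.16 for plasma proteins, −0.06 for drug metabolism, −0.22 for macrophages and −0.07 for liver cancer genes; Ikzf1 had 0.57, Mmp15 0.86, Kng2 0.54 and Brca2 0.63.

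Across circular RNAs, which are not independent replicates, the log2 changes of CCl4 against control and of CCl4+PZH against CCl4 had a correlation of −0.486. Unchanged groups that share the CCl4 libraries gave −0.502 in simulation (95% range −0.583 to −0.421). The simulation gave all groups the same spread for each circular RNA, which by itself sets a value near this one. It therefore cannot show that the shared libraries account for the whole measured correlation. The covariance was −0.232 against a simulated −0.215, a difference of −0.0176. With the CCl4 libraries split between the comparisons, the correlation was −0.116 on average over 20 splits (−0.186 to −0.046), and the mean covariance was −0.0732. Unchanged groups would on average give no correlation in such splits. The splits reuse the same mice and were not tested, so opposite changes across circular RNAs are neither shown nor excluded.

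CCl4+PZH livers differed from controls in 1 circular RNA, that on chromosome 3, above 0 in 6 of 6 treated livers and listed at 0 in 6 of 6 controls. Its mean in CCl4+PZH was 11.5-fold the floor averaged over the controls, and its fitted log2 was 5.09 (limma SE 0.80, adjusted p = 1.01e-07). Without control 2, Ilkap and Zc3h7a also passed, 3 in all. Values that did not pass were measured for Arhgap32, listed at 0 in 6 of 6 controls and at 0.4 ± 0.148 CPM in CCl4+PZH (SD, n = 6; limma adjusted p = 0.135), for Ilkap (log2 2.27, adjusted p = 0.276), for Tlcd4 (−2.26, adjusted p = 0.468) and for Zc3h7a (2.05, adjusted p = 0.474). The mean of Arhgap32 lay below the floor of 3 reads in controls 1, 2 and 4 (0.408, 0.918 and 0.581 CPM) and above it in controls 3, 5 and 8. Rere had log2 −1.49, Phkb 1.24, Metap1d 1.49, Ikzf1 1.59 and Slco1b2 (141663578 to 141672313) −1.45 (adjusted p = 0.763 each).

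No list passed camera against control. Medians were −0.37 for lipid genes (1 positive of 5, adjusted p = 0.362), −0.59 for bile acid genes (adjusted p = 0.362; with 1 circular RNA per host camera pointed up, adjusted p = 0.968), 0.11 for amino acid genes, −0.17 for well-studied hosts and 0.17 for RNA processing genes. Untested lists had medians of 0.08 for plasma proteins, −0.59 for drug metabolism, 0.53 for macrophages and −0.27 for liver cancer genes. Members of smallest p in the first 3 of these were Kng2 (0.33), Ces1c (−1.55) and an Adgre1 circular RNA at 57419322 to 57420524 of chromosome 17 (1.35), and those of tested lists not yet named were Dpyd (1.17), Mlxipl (−0.99) and Eed (1.08). Ikzf1, the only lymphocyte member, did not pass over all tested (limma adjusted p = 0.763); adjusted over the list alone 1 passed, this one, where a list of 1 leaves p as it is; Mmp15 had 1.34 and Brca2 0.71.

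The changes of CCl4 and of CCl4+PZH, both against control, had a correlation across circular RNAs of 0.659, where unchanged groups sharing the controls gave 0.496 (0.418 to 0.568). The covariance was 0.366 against a simulated 0.211, a difference of 0.155. This simulation also gave all groups the same spread, so its values do not allow for a group that varied more. With the controls split, the correlation was 0.217 on average over 20 splits (0.119 to 0.308), and the mean covariance was 0.162. The chromosome 3 circular RNA was called up in both, where independent lists would share 0.00461 and simulated unchanged groups shared 0.01 on average.

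Presence, taken as a value above 0, passed Fisher's exact test with adjustment for 0 circular RNAs in each comparison, with 3, 0 and 3 at an unadjusted p under 0.05. The smallest p that 6 against 6 allows is 0.00216, reached by Vrk2 in CCl4 against control (adjusted p = 0.939) and by Arhgap32 and the chromosome 3 circular RNA in CCl4+PZH against control (adjusted p = 0.47). Such a p cannot pass over 434 tests unless many circular RNAs reach it. Against control, all 3 in each comparison were present more often. Every listed circular RNA was above 0 in at least 9 of 18 libraries. One present in a single group of 6 could therefore not be listed, while one present in both CCl4-exposed groups could. The direction of these changes thus cannot be read from the table.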

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

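In groups of 6, a mouse was picked out here when its gap to the nearest other value exceeded the 95% limit of Dixon's test. Of 150 groups of values examined, 17 had such a mouse, where chance gives 7.5 for normally distributed values. These values hold many zeros, and a single non-zero value against 0 in the other 5 is always picked out, as in 6 of the 17, so the 2 numbers cannot be compared. The tests of explanations in this part were chosen after the results were seen, except the random deals of zeros.

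For the chromosome 3 circular RNA, CCl4 2 was listed at 0 while the other 5 CCl4 livers were above 0 and reached 9.19 CPM. For Zc3h7a, control 2 stood at 2.75 CPM against 0 in the other controls, and CCl4 4 at 0 against 1.47 CPM or more. For Psd3 control 3 stood at 0.135 CPM, for Adgre1 control 1 at 0.272 CPM, for Arih1 CCl4 7 at 0.0874 CPM, for Cyp1a2 CCl4 1 at 0.143 CPM and for Slco1b2 (141648489 to 141657606 of chromosome 6) CCl4 7 at 0.35 CPM, each against 0 in the rest of its group. For Mlxipl CCl4 5 stood at 0.612 CPM, the others reaching 0.0874 CPM. For Ube2g2 CCl4 5 stood at 0.489 CPM, the others reaching 0.0919 CPM, and for Tlcd4 control 4 at 5.23 CPM, the others reaching 2.18 CPM. Values of 0 stood apart for Pon1 in control 3, Gm9762 in CCl4+PZH 1, Lrrc28 in CCl4+PZH 3, Gramd1c in CCl4 7, and Ube3a and Alg12 in CCl4 8; the other CCl4 livers had at least 2.45 CPM of Ube3a, 2.30 CPM of Gramd1c and 0.978 CPM of Alg12.

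The circular RNA on chromosome 3 was listed at 0 in all 6 controls and above 0 in 11 of 12 livers exposed to CCl4. Depth of the controls is set against by their reads: at the lowest non-zero exposed CPM, a control would hold at least 7.19 reads. This number assumes reads in proportion to the implied total, which the recovered reads did not follow. Recovered reads per library were on average no fewer in controls, at 1588 against 1231 in CCl4 and 1481 in CCl4+PZH. A difference between the deposits of controls is set against by controls 1, 5 and 8, deposited with the exposed livers, which held 0 reads. Zeros that strike abundant circular RNAs library by library left a whole group at 0 in 0.55% of 10000 random deals. The deals covered 15 abundant circular RNAs, that on chromosome 3 included. The low share argues against zeros that fall at random over the libraries. The deals cannot speak to zeros that follow a group or a step of the calling or filtering. An effect of CCl4 exposure stays open as a hypothesis, and so do reads from repeated sequence, a strain variant and a mix-up of libraries, which were not tested.

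Abundant circular RNAs were often listed at 0: where 10 or more reads were expected from the totals of the circular RNA and the library, 35 of 305 values were 0 and 3 were a single read. Counting error gives 0.00229 zeros there. One failing library is set against by their spread, since the library with most of them, control 4, held 22.9% and 15 of 18 libraries held some. Smooth variation between animals, in the form of the fitted model, is set against by simulated draws from it. The ratio of zeros to single reads was 11.7, above the 2.25 that bounds 95% of these draws. The 35 zeros stood above a simulated median of 6 and upper bound of 11. These bounds rest on the fitted model, so smooth variation of another form stays open. A step of the calling or filtering that removes junctions per library could also leave such zeros, and was not tested. Expected reads took no account of group, so the 35 zeros include those of the chromosome 3 circular RNA in all controls.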

How the results depend on the processing

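Alternatives named here as added were chosen after seeing the data. The 3 filters removed nothing, so they say nothing of stability. The count for CCl4+PZH against CCl4, the opposite moves and the lists called stayed at 0 under every alternative run. For CCl4 against control (3 called) the count was 1 with a pseudocount of 1 and of 10 times the main one, 0 by the exact rank test, whose smallest p of 0.00216 cannot pass over 434 tests unless many reach it, 5 by edgeR with TMM, 2 by DESeq2 (Zc3h7a lost, adjusted p = 0.57), 1 with controls 2, 3 and 4 alone and 2 with controls 1, 5 and 8 alone (Ttc39c lost, adjusted p = 0.189); it was 2 with a smaller pseudocount and with the 2 groups alone (Ttc39c lost), and 4 with array weights (Psd3 gained) and quantile normalization (Tlk1 gained); added alternatives gave 5 scaled to the table's own reads, 0 with abundant zeros missing, 1 by edgeR with implied totals, 0 with single-copy coding hosts (Zc3h7a and Ttc39c with fold changes as in the main fit, adjusted p = 0.0512 each), and 2 without controls 3 and 4 (Zc3h7a lost). For CCl4+PZH against control (1 called) it was 3 with array weights, 0 by the rank test with the same limit, 2 by edgeR with TMM and 2 with implied totals, 0 with zeros missing and 0 with single-copy coding hosts; in both comparisons the chromosome 3 circular RNA is left out of the last by construction, and cannot be tested with zeros missing. The cause was not tested for the others. Leaving out each library gave 1 to 6 calls for CCl4 against control, 0 to 0 for CCl4+PZH against CCl4 and 1 to 3 for CCl4+PZH against control.

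With the replicate number as a block, 1 was called for CCl4 against control, and the summed CPM difference between CCl4+PZH and control turned to 11.7 over same-number pairs. The numbers do not pair the mice: of 13 same-number pairs, 0 had a correlation over 0.1 (−0.154 to 0.0794) and 3 matched their own number best.

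Leaving out each library, the difference in detected circular RNAs ran from −14.9 to 2.67 for CCl4 against control, 13.5 to 26.9 for CCl4+PZH against CCl4 and 6.57 to 24.2 for CCl4+PZH against control; that in summed CPM ran from −133.9 to −32.1, 46.4 to 77.4 and −74.9 to 27.0, the last turning without control 4.

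Turned values, none past the threshold, were as follows. With zeros missing, Zc3h7a had −0.16 in CCl4 and −0.23 in CCl4+PZH against control 2 alone, since the other 5 controls are removed as zeros, which ends the difference by construction. The chromosome 3 circular RNA then had −0.18 in CCl4+PZH against CCl4, where edgeR with TMM gave −0.34 and DESeq2 −0.33. Leaving out each library took its value from −0.18 to 1.04 and Brca2 in CCl4 against control from −0.34 to 0.32; with controls 2, 3 and 4 alone Brca2 had −0.088. Kng2 in CCl4 against control had 0.00247 with the large pseudocount, 0.15 by edgeR with TMM, 0.11 by DESeq2 and 0.083 with implied totals. Bckdhb (83988776 to 84012619) in CCl4+PZH against CCl4 had 0.0037 with the large pseudocount, 0.24 with the replicate block, 0.091 with implied totals and −0.35 to 0.22 with each library left out. Without controls 3 and 4, Mmp15 in CCl4 had −0.00604 and Eed in CCl4+PZH −0.11 against control. The cause was not tested. Apart from single libraries left out and the 3 filters, the call of Zc3h7a in CCl4 was lost in 9 of 20 alternatives and its value turned in 1, that of Ttc39c was lost in 11 of 20, and that of the chromosome 3 circular RNA was lost in 1 of 18, the rank test, in each comparison with control. Of 1239 values of those not called by the main fit, 8 gained a call and 14 turned. With 1 circular RNA per host, camera turned up for the bile acid list in CCl4 and CCl4+PZH against control; that for the RNA processing list in CCl4 turned down with quantile normalization and scaled to the table's own reads.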

Other observations

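The tests of other splits and of the first hypotheses here were chosen after the results were seen; the test on pairs that share no end was fixed before its result.

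Circular RNAs of the same host gene had log2 changes with a positive mean product in CCl4 against control. Over 66 pairs in 44 host genes, such as the 3 of Ttc39c (all negative), the 3 of Rere (all negative) and the 3 of Adgre1 (all positive), the mean product was 0.277, one-sided permutation p = 6e-04, adjusted p = 0.0018 over 3 comparisons. The permutation shuffled circular RNAs and not mice. Its p therefore does not measure the spread between mice, and cannot by itself show an effect of CCl4. The permutation p was 0.1345 for CCl4+PZH against CCl4 and 0.1325 against control, so neither passed. The share of pairs of the same sign was 62.1%, 63.6% and 43.9% in these comparisons, so the share does not set CCl4 against control apart; the differences between comparisons were not tested. Reads shared at a common junction end are set against as the whole cause, since the 33 pairs that share no end had a mean product of 0.374 (permutation p = 0.0021). Leaving out Ttc39c, the host that mattered most, gave permutation p = 0.009. A change in the host transcripts is a candidate explanation that was not tested, since host gene levels were not analysed here.

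Whole profiles also set controls apart from CCl4 livers. The mean correlation between libraries was 0.297 within the groups and 0.213 between them, with an exact one-sided permutation p of 0.00216, the smallest that 924 splits can give (adjusted p = 0.00325). Without the called circular RNAs the difference fell from 0.0846 to 0.0553 and the exact p stayed at this lower limit. With controls 1, 5 and 8 alone the exact p was 0.0119, the smallest of 84 splits. CCl4+PZH and control gave the same exact p of 0.00216 (0.306 within, 0.259 between), but 0.131 with controls 1, 5 and 8 alone; without the called circular RNAs the difference fell from 0.0466 to 0.0251 (exact p = 0.0303, adjusted p = 0.0455). CCl4+PZH and CCl4 gave 0.294 and 0.283 (exact p = 0.145), which does not show that these profiles are alike.

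The recovered reads did not rise with the implied library total. The slope of log2 reads on log2 total was −0.258 (95% interval −0.578 to 0.0627) over 18 libraries, −0.06 (−0.545 to 0.425) in the 15 of the first deposit, and −0.245 (−0.575 to 0.0841) within groups. Pearson's r was −0.392 (permutation p = 0.109), Spearman's rho was −0.232 (permutation p = 0.353), and r was −0.367 without controls 2 and 3. In the first deposit r was −0.0739 (permutation p = 0.793) and rho −0.0107 (permutation p = 0.975).

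Chance is unlikely for the count of CCl4 against control but is not excluded. Of 100 splits of the 12 libraries, 1, the real one, gave 3 calls, and the highest other gave 2. That is the smallest share that 100 splits can give. At least 1 call was made in 10 splits other than the real one, and leaving out each library gave 1 to 6. Chance stays open for CCl4+PZH against control, where 17 of 100 splits gave at least the real count of 1. The highest other gave 7, which may point to a structure of the samples. With controls 1, 5 and 8 alone, controls 2, 3 and 4 alone, or the replicate number as a block, 1 was called. The source of the calls in the other splits was not tested. For CCl4+PZH against CCl4 the real count was 0, as large as in 100 of 100 splits, with 0 as the highest other. The counts of lists called and of opposite moves were 0, reached by 100 of 100 splits, with a highest other of 1, 1 and 0 for the lists of the 3 comparisons and 0 for opposite moves.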
